A study of Mus musculus with 24 samples.

How the data were processed

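The data are RNA-seq counts from 24 libraries of natural killer (NK) cells, sorted from B16F10 melanoma tumours of female B6 mice at day 14. Per the labels' protocols, 100 cells per library were sorted into lysis buffer. Polyadenylated RNA was copied with the SMART-Seq v4 kit, which gives amplified full-length cDNA, and libraries were made with Nextera XT. This chemistry keeps no strand information and adds no molecular identifiers, so counts are of amplified fragments and intervals and floors cover counting error only. The labels give melanoma as the cell type, while the design text names the sorted NK populations, and the grouping used here follows the titles.

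The authors deposited raw counts per Ensembl gene, 1 column per library, with no normalization. The submitters' processing notes name the genome build GRCm38 and the tools HTSeq and Picard, without versions. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The table held 53471 entries, and 53465 gene identifiers after repeats were removed. Symbols came from the table itself. The 3546 genes with no symbol of their own held 0.175% of all counts and stayed in the tests. Gene positions and overlaps were taken from GENCODE M21 for GRCm38, in which all 269 named genes were found, 83 of them with exons that overlap another gene. Reads in such overlaps, and reads shared within families such as Klra, Gzm, Ly6, Ms4a, Serpina3, the class I H2 genes and the T cell receptor constant genes, cannot be assigned with certainty from a count table.

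Total counts per library ran from 1213914 to 2671533, with a median of 2213433. A floor of 3 counts corresponded to between 1.12 and 2.47 CPM, the count scaled to library size. Replicate libraries differed by far more than counting error, with a chi-square per degree of freedom between 10.3 and 32.3 over the 60 pairs within populations. The labels do not say whether the replicates of a population came from separate animals, so p-values measure only the spread between samples. In the titles each replicate number, written with an M, stands on 1 library of each of the 4 populations. What M marks is not given, and the main fit did not pair libraries by it. Each of the 4 populations, CD11b+CD69-, CD11b+CD69+, CD27+CD69- and CD27+CD69+, had 6 libraries.

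Tests used the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, in 1 fit of 4 group means to all 24 libraries. Genes were kept by filterByExpr with its minimum count of 10, which left 10536 genes. Library sizes were scaled by TMM (factors from 0.958 to 1.06), and dispersions and the quasi-likelihood fit were robust. Comparisons were CD69+ minus CD69- within CD11b+ and within CD27+ cells, CD27+ minus CD11b+ within CD69- and within CD69+ cells, and the difference between the CD69 differences. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Changes of single genes are log2 fold changes of this fit, given as differences on the log2 scale. CPM are TMM-scaled and given as mean ± SD. Where libraries are counted as higher or lower, each was set against the median of the other population. Where a group had 0 counts, its fold change is given as a lower bound against a floor of 3 counts over the 6 libraries of the group. Where it had 1 to 3 counts, the ratio of counts is given with a 95% interval. Fitted fold changes of such genes depend on the prior count of the edgeR fit, left at its default, and are not used as sizes.

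Sets of genes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The 33 lists cover NK cell states, IL-2 and IL-15 signalling, effector programs, stress and metabolism, a quality class and other cell types, and 27 had the 3 measured members that a test needed. The 24 pan-leukocyte genes used to weigh dilution of NK RNA were a further set, written before that test. The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

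That rule names Flt3l, Itgam, Cd27, Cd69, Ncr1, Klrb1c, Il2ra, Il2rb, Il2rg and Il15ra in every comparison. It adds, for each comparison, the 8 largest rises and 8 largest falls past the threshold. Those genes needed a mean of 10 CPM over the libraries compared, counts in 5 of 6 libraries of the higher population, and 5 of 6 libraries above the median of the lower one. For the difference between CD69 differences it adds 3 genes each way with a mean of 10 CPM over all libraries. It also adds up to 4 members with the smallest p of each list described. Clone-named genes, pseudogenes and genes with no symbol were excepted. Results of 2 genes that the rule names are not reported here.

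The edgeR, limma and DESeq2 1.42.0 tests were tested on simulated counts with 200 changed genes before use. Alternatives were DESeq2 size factors, no low-count filter, a mean of at least 5 CPM, the DESeq2 Wald test, limma-voom with sample weights, a fit to only the 2 populations compared, the replicate number as a block, thinning to 1213914 counts, melanoma and macrophage marker levels as covariates, and leaving out each replicate number in turn. There were 3 further alternatives chosen after seeing the data: fibroblast and melanoma marker levels as covariates, omission of the 3 CD27+CD69- libraries with most fibroblast and melanoma RNA, and a test of only genes over 10 CPM in the other 2 populations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.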

Results

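RNA was measured in NK cells, innate lymphocytes that kill tumour cells and secrete cytokines, sorted from tumours of B16F10, a mouse melanoma line. Cells were sorted by CD11b, an integrin chain of mature NK cells, by CD27, a TNF receptor family member of less mature NK cells, and by CD69, a lectin that appears early after activation and holds cells in tissue. The 4 populations had 6 libraries each. Mean total counts per library were 2359132.5 ± 209869 in CD11b+CD69-, 2240677 ± 235371 in CD11b+CD69+, 1880828 ± 438493 in CD27+CD69- and 2096326 ± 212958 in CD27+CD69+ libraries (SD, n = 6 each). The CD27+CD69- libraries had the most genes detected, 13829 ± 459, against 11850 ± 150 (CD11b+CD69-), 12026 ± 86.9 (CD11b+CD69+) and 12710 ± 311 (CD27+CD69+). In the order CD11b+CD69-, CD11b+CD69+, CD27+CD69- and CD27+CD69+, macrophage genes summed to 113 ± 39.1, 180 ± 64.5, 330 ± 120 and 308 ± 78.9 CPM. Mitochondrial transcripts made up 0.751 ± 0.0861, 0.894 ± 0.219, 1.12 ± 0.350 and 1.10 ± 0.0986% of counts in the same order. Of the 10536 genes tested, 1483 differed among the 4 populations by edgeR's quasi-likelihood test.

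The study is about production by NK cells of FLT3LG, the cytokine encoded by Flt3l that supports the development of dendritic cells, under IL-2 and IL-15. Flt3l was expressed in all 4 populations and no comparison found a difference. Flt3l (ENSMUSG00000110206, chromosome 7, 45129788 to 45136432, minus strand, GRCm38) had 2476 counts over the 24 libraries, with 17 to 169 in each. Its level was 50.1 ± 10.2 CPM in CD11b+CD69-, 41.7 ± 16.5 in CD11b+CD69+, 42.2 ± 19.8 in CD27+CD69- and 59.1 ± 14.7 in CD27+CD69+ libraries. The log2 difference of CD69+ from CD69- libraries was -0.27 (SE 0.30) in CD11b+ cells, with adjusted p = 0.792 and 4 of 6 libraries lower. It was 0.48 (SE 0.30) in CD27+ cells, with adjusted p = 0.659 and 5 of 6 libraries higher. CD27+ libraries differed from CD11b+ libraries by -0.24 (SE 0.30, adjusted p = 0.705) among CD69- cells and by 0.51 (SE 0.30, adjusted p = 0.593) among CD69+ cells. The CD69 difference itself differed between CD27+ and CD11b+ cells by 0.75 (SE 0.42, adjusted p = 0.647). A difference that did not pass does not show that the levels were equal. Gm45713, which overlaps Flt3l on the same strand, was listed at 0 counts in all 24 libraries, and how reads in their shared exons were counted is not given in the sources used here. With fibroblast and melanoma marker levels as covariates the sign changed in CD27+ cells (-0.17) and among CD69- cells (0.57).

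The transcripts of Itgam and Cd27 followed the sort. Itgam (CD11b; ENSMUSG00000030786, chromosome 7, 128062640 to 128118491) was lower in CD27+ than in CD11b+ libraries by a log2 difference of -2.86 (SE 0.52) among CD69- cells and -3.30 (SE 0.54) among CD69+ cells. Cd27 (ENSMUSG00000030336, chromosome 6, 125232622 to 125237010) was higher by 1.66 (SE 0.23) and 1.28 (SE 0.23). Cd69 (ENSMUSG00000030156, chromosome 6, 129267325 to 129275436) stood at 607 ± 253 CPM in CD11b+CD69-, 1112 ± 59.4 in CD11b+CD69+, 735 ± 188 in CD27+CD69- and 1173 ± 129 in CD27+CD69+ libraries. Cd69 transcript was thus present in the populations sorted as negative for the protein.

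**Figure D1:**
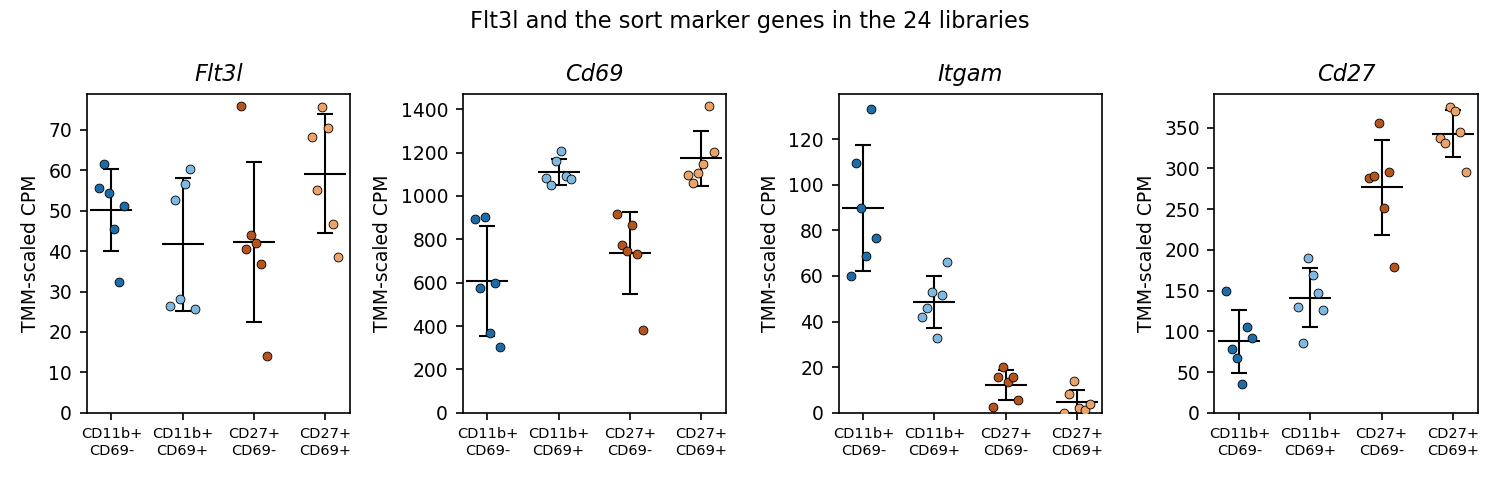
Flt3l, Cd69, Itgam and Cd27 in TMM-scaled CPM for each of the 24 libraries, by population, with mean ± SD (n = 6). Flt3l means lie between 41.7 and 59.1 CPM in all 4 populations, while Itgam and Cd27 follow the sort.

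The comparison of CD69+ with CD69- cells among CD11b+ cells shows how mature NK cells with this activation and retention marker differ from those without it. CD69+ cells had more interferon-induced transcripts and more of the cytokines Xcl1 and Csf2. The lists of mature NK cell genes and of egress genes, which let lymphocytes leave tissue, fell, although 5 of 12 and 2 of 9 members passed. Cd69 itself rose by 0.87 on the log2 scale (SE 0.20, adjusted p = 0.0135, 6 of 6 libraries higher), and did not pass without replicate 2, 4 or 5 (0.87, 0.73 and 0.87, adjusted p = 0.0692, 0.105 and 0.0634).

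Interferon-induced genes gave the 3 largest named rises. Ifi44 (ENSMUSG00000028037), an antiviral gene, had 75.1 ± 45.0 CPM in CD69+ libraries and 0 counts in CD69- libraries, at least 345-fold higher. Rsad2, which encodes the antiviral enzyme viperin, was at least 154-fold higher and Ifi211, a DNA-sensor family gene, at least 124-fold higher, both from 0 counts and in 6 of 6 libraries. Of 22 measured genes of the type I interferon response, 14 rose and 0 fell, or 19 rose when adjusted over the list alone (camera adjusted p = 1.53e-19). Besides Ifi44, these included Bst2 (tetherin, which holds virus particles at the membrane), up by 1.69, Isg20 (an antiviral exonuclease), up by 3.04, and Usp18 (a brake on interferon signalling), up by 2.74. Ifit3, an adaptor of antiviral signalling, rose by 4.56 (SE 0.91, adjusted p = 0.00467, 6 of 6 libraries).

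Transcripts of mature NK cells fell. Of 12 genes of the mature list, 5 fell and 0 rose, or 11 fell when adjusted over the list alone (camera adjusted p = 3.75e-20). Cma1, a mast cell chymase gene also transcribed in NK cells, fell by 3.47 (SE 0.45), from 871 ± 189 to 78.6 ± 16.9 CPM. Cx3cr1, the fractalkine receptor of circulating NK cells, fell by 3.88 (SE 0.87), from 124 ± 67.9 to 8.22 ± 12.7 CPM. Irf8, a transcription factor of NK effector function, fell by 0.70 and Ly6c2, a surface antigen of resting mature cells, fell by 1.21. Among 9 egress genes, 2 fell and 0 rose, or 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 3.97e-07): Klf2, the transcription factor that maintains exit receptors, fell by 1.11 and S1pr5, a sphingosine phosphate receptor for exit, fell by 1.53. Rasgrp2, an integrin activator of circulating lymphocytes, fell by 2.58 and Sgk1, a kinase downstream of PI3K, fell by 2.18.

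Transcripts of less mature and tissue-resident cells rose. In the immature list 6 of 14 genes rose and 0 fell, or 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.12e-06), among them Ltb (lymphotoxin beta, a lymphoid organizer), up by 2.30, Ctla2a (a cathepsin inhibitor), up by 0.97, Emb (an adhesion protein), up by 1.01, and Cd160 (a receptor of the immunoglobulin family), up by 1.19. In the list for innate lymphoid cells type 1 (ILC1) and tissue residency 3 of 15 rose and 0 fell, or 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00147): Ccr2, a chemokine receptor for entry into inflamed tissue, by 1.04, Gpr183, an oxysterol receptor, by 1.92, and Rgs1, a brake on chemokine signalling, by 0.56. Immediate early genes fell, 3 of 22 with 0 rising, or 4 when adjusted over the list alone (camera adjusted p = 1.02e-07): Ier2 at -0.86, Zfp36, an mRNA decay factor, at -0.91 and Nr4a1, a receptor gene induced by antigen receptor signals, at -1.18. All lists named so far for these cells also passed with an estimated correlation, with adjusted p from 0.00028 for the mature list to 0.0478 for the immediate early list.

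Secreted factors moved both ways. Xcl1 (ENSMUSG00000026573, chromosome 1), the chemokine that attracts cross-presenting dendritic cells, rose by 2.15 and Csf2 (ENSMUSG00000018916), the cytokine GM-CSF for myeloid cells, by 6.21 (SE 1.24, adjusted p = 0.00353, 5 of 6 libraries). Ccl5, a chemokine for T cells and dendritic cells, fell by 0.98. Of 8 measured factors acting on dendritic cells, 2 rose and 1 fell, or 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.138), where the median was -0.29 and the mean 0.83. Of 11 effector cytokines and chemokines, 4 rose and 2 fell, or 4 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.331, median -0.32, mean 0.89). Spp1, which encodes osteopontin, rose by 4.34 (SE 0.96), with 285 ± 537 CPM in CD69+ libraries.

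Cytotoxic genes moved both ways. Gzmc (ENSMUSG00000079186, chromosome 14), a granzyme of strongly stimulated lymphocytes, rose by 4.29, while Prf1 (perforin, which opens target membranes) fell by 0.77 and Fasl (a death ligand) fell by 0.55. Of 12 cytotoxic genes, 1 rose and 2 fell, or 2 rose and 5 fell when adjusted over the list alone; camera put the list down (adjusted p = 0.0468, median -0.30), the mean was 0.33, and the call was lost with adjusted p = 0.446 with an estimated correlation. Activating receptors showed no set difference, with 1 of 13 up (Crtam, an adhesion receptor of activated lymphocytes, by 4.34) and 1 down (Klrc2, an activating NKG2 receptor, at -0.63), or 1 up and 3 down when adjusted over the list alone (camera adjusted p = 0.179).

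IL-2 and IL-15 signalling gave mixed changes. Il2ra, the high-affinity IL-2 receptor chain, had 24.3 ± 22.7 CPM against 1.78 ± 4.36, higher in 6 of 6 libraries, but did not pass (log2 difference 3.73, SE 1.06, adjusted p = 0.0555). All its CD69- counts came from replicate 3, and without replicate 3, against 0 counts, Il2ra passed with adjusted p = 0.000862. Il2ra also passed with DESeq2, limma-voom, thinned counts, melanoma and macrophage covariates, and among genes over 10 CPM in CD27+ cells (adjusted p from 0.00562 to 0.0446). None of the 14 receptor and JAK-STAT5 genes passed, 1 rose when adjusted over the list alone (camera adjusted p = 0.343). Among 22 STAT5 target genes 2 rose and 2 fell, or 7 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.944): Tnfrsf9 (the co-stimulatory receptor 4-1BB) rose by 1.22 and Odc1 (polyamine synthesis) by 0.92, Ccnd3 (a cyclin) fell by 0.77 and Osm (oncostatin M, an IL-6 family cytokine) fell by 1.49.

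Ribosomal protein genes rose, 7 of 24 with 0 falling, or 18 when adjusted over the list alone (camera adjusted p = 1.31e-13; adjusted p = 0.246 with an estimated correlation), with Rps19, a small-subunit protein, up by 0.64. The heat shock and glycolysis lists were called up with 0 members of 13 and of 14 past the threshold in either count (camera adjusted p = 0.0152 and 0.00894; both adjusted p = 0.579 with an estimated correlation). Other named rises were Cd83, an activation marker (6.02), and Ly6a, an interferon-inducible surface antigen (4.61). Other named falls were Cym, a protease (-2.39), Stmn1, a microtubule regulator of dividing cells (-2.44), and As3mt, an arsenic methyltransferase (-1.97). The test called 289 genes, 173 higher and 116 lower, and 1460 had an unadjusted p under 0.05. The excess of rises turned in limma-voom (146 higher, 168 lower) and in the fit to only the 2 populations (177 and 196). T cell marker genes summed to 1476 ± 151 CPM in CD69+ and 1120 ± 123 in CD69- libraries, and 1 of 11 rose, Cd3g by 3.72 (3 when adjusted over the list alone; camera adjusted p = 0.0595). Among named genes and the 4 members of each list with the smallest p, 52 passed the threshold. Of these, 25 passed in every alternative fit that tested them. In limma-voom 12 of them did not pass, Csf2, Cd83, Ly6a, Rsad2, Spp1 and Stmn1 among them.

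The same comparison among CD27+ cells asks what distinguishes CD69+ cells within the less mature population. CD69+ cells had more Gzmc, Xcl1 and Cish. Of the NK identity and inhibitory receptor lists a few members passed (2 of 16 and 2 of 13), beside more stromal RNA in the CD69- libraries. The 8 largest named falls were of genes with 0 counts in CD69+ libraries, collagen and matrix genes among them. Cd69 was higher in 6 of 6 libraries by 0.67 (SE 0.20) and did not pass (adjusted p = 0.0907), although it did with DESeq2, limma-voom and the replicate number as a block (adjusted p = 0.0456, 0.0252 and 0.0448).

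Gzmc rose by 4.70 (SE 0.77, adjusted p = 0.00107), from 14.6 ± 6.70 to 387 ± 411 CPM, in 6 of 6 libraries. Ms4a4c (ENSMUSG00000024675), a membrane protein of the CD20 family in activated lymphocytes, rose by 1.91 (SE 0.18, adjusted p = 7.31e-07, 6 of 6). Xcl1 rose by 1.14 (SE 0.24, adjusted p = 0.00700, 6 of 6) and Cst7, an inhibitor of the cathepsins that activate granzymes, by 1.12 (SE 0.15, adjusted p = 8.29e-05, 6 of 6). Cish, a STAT5-induced brake on IL-15 signalling, rose by 1.10 (SE 0.25, adjusted p = 0.0157, 5 of 6). Il2rg, the receptor chain shared by IL-2 and IL-15, rose by 0.51 (SE 0.11, adjusted p = 0.0131, 6 of 6), and not past the threshold without replicate 4 or 5 (0.49 and 0.47, adjusted p = 0.0775 and 0.0724), in a fit to only the 2 populations (0.49, adjusted p = 0.0983), or with melanoma and macrophage (0.31, adjusted p = 0.158) or fibroblast and melanoma covariates (0.34, adjusted p = 0.999). Il2ra was at 23.8 ± 8.53 against 3.22 ± 3.24 CPM, higher in 6 of 6 libraries, with adjusted p = 0.185, and passed with limma-voom (adjusted p = 0.0116) and in a fit to only the 2 populations (0.0467). Spin2c (a chromatin reader, 1.58), Phactr3 (a phosphatase regulator, 1.19) and Lilr4b (a leukocyte immunoglobulin-like receptor, 1.33) also rose. Ccl3, a chemokine for monocytes, fell by 2.23. It and Xcl1 were the members past the threshold in either count among 8 factors acting on dendritic cells (camera adjusted p = 0.999), and among 11 effector cytokines, where 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.444).

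STAT5 target genes rose, 3 of 22 with 0 falling, or 9 when adjusted over the list alone (camera adjusted p = 1.19e-05; adjusted p = 0.0870 with an estimated correlation): Tnfrsf9 by 0.85, Cish, and Myc, a driver of growth, by 0.72. In the receptor and JAK-STAT5 list 1 of 14 rose, Il2rg, and 1 when adjusted over the list alone (camera adjusted p = 0.0924). NK identity genes rose, 2 of 16 with 0 falling, or 11 when adjusted over the list alone (camera adjusted p = 4.16e-11, and adjusted p = 0.0459 with an estimated correlation): Ctsw, a granule protease, by 0.52 and Klra9, a Ly49 receptor, by 0.94. Inhibitory and checkpoint receptors rose, 2 of 13 with 0 falling, or 5 when adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.0299 with an estimated correlation): Klra7, a Ly49 receptor for class I molecules, by 0.51 and Cd96, a nectin-family receptor, by 0.61. Activating receptors rose, 1 of 13 with 0 falling (Slamf7, a self-ligand receptor, by 0.79), or 10 when adjusted over the list alone (camera adjusted p = 3.05e-09; adjusted p = 0.0590 with an estimated correlation). These rises lay beside a lower share of stromal RNA: the 8 fibroblast genes summed to 27.5 ± 42.7 CPM in CD69+ and 4338 ± 3321 CPM in CD69- libraries.

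Cytotoxic genes rose as a list, 2 of 12 up (Gzmc, Ctsw) and 1 down (Gzma, a granzyme of resting NK cells, at -0.55), or 4 up and 3 down when adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.313 with an estimated correlation). Mature genes fell, 2 of 12 with 0 rising, or 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00207; adjusted p = 0.146 with an estimated correlation): Gzma, and Emilin2, a matrix glycoprotein, at -3.73. Of 22 immediate early genes 2 fell and 0 rose, and the same numbers held when adjusted over the list alone (camera adjusted p = 0.00342; adjusted p = 0.292 with an estimated correlation): Egr1, a growth-factor-induced transcription factor, at -1.22 and Nr4a1 at -0.96. Interferon genes were called up with 0 of 22 past the threshold, or 2 when adjusted over the list alone (camera adjusted p = 2.05e-05; adjusted p = 0.146 with an estimated correlation). Ribosomal protein genes rose, 2 of 24 (Rpl13, a large-subunit protein, by 0.41 and Rps18, a small-subunit protein, by 0.37), or 22 when adjusted over the list alone (camera adjusted p = 1.19e-19; adjusted p = 0.117 with an estimated correlation). The ILC1 and residency list rose with 1 of 15 past the threshold in both counts, Rgs1 by 0.76 (camera adjusted p = 0.0110; adjusted p = 0.117 with an estimated correlation). Hypoxia genes fell, 1 of 16 (Adm, the vasodilator peptide adrenomedullin, at -6.04), or 7 when adjusted over the list alone (camera adjusted p = 0.000123; adjusted p = 0.146 with an estimated correlation). With 0 members past the threshold over all genes, camera also called the immature, T cell, oxidative phosphorylation and NF-kB lists up and the heat shock, glycolysis and cell cycle lists down. Adjusted over the list alone, 1 NF-kB gene rose, 1 cell cycle gene fell and no other member passed. Their adjusted p ran from 0.00107 to 0.0438, and from 0.146 to 0.495 with an estimated correlation. The glycolysis call reversed, to up, with fibroblast and melanoma covariates (adjusted p = 0.0165) and with melanoma and macrophage covariates (adjusted p = 0.0243). With fibroblast and melanoma covariates the heat shock, NF-kB, interferon, hypoxia and cytotoxic lists changed sign and did not pass (adjusted p = 0.308, 0.420, 0.824, 0.420 and 0.912).

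The largest falls were of transcripts that CD27+CD69- libraries held in quantity. Gpx3, a secreted glutathione peroxidase, was at least 2071-fold lower, Col1a2, a fibrillar collagen chain, at least 1817-fold, Anxa3, a membrane-binding annexin, at least 946.5-fold, and Cd34, an adhesion antigen of progenitor, vessel and stromal cells, at least 884-fold. Sod3 (extracellular superoxide dismutase), Mmp2 (a matrix protease), Nid1 (a basement membrane protein) and Igfbp7 (a growth factor binding protein) were at least 770.2-fold, 689.9-fold, 495-fold and 479-fold lower, each with 0 counts in CD69+ libraries. Of 3 measured fibroblast genes 2 fell, or 3 when adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.188 with an estimated correlation). The test called 195 genes, 58 higher and 137 lower, and 1154 had an unadjusted p under 0.05. Among genes over 10 CPM in CD11b+ cells it called 35 higher and 45 lower, without the 3 CD27+CD69- libraries with most stromal and melanoma RNA 28 and 40, and with no filter 54 and 351. Among named genes and the 4 members of each list with the smallest p, 34 passed the threshold. Of these, 4 passed in every alternative fit that tested them, and 30 did not pass with fibroblast and melanoma marker levels as covariates.

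The CD69 comparisons of CD11b+ and CD27+ cells share no libraries, but they share the replicate numbers and 1 fit with 1 spread estimate per gene. Both called 23 genes higher, against 0.952 expected if calls fell on genes independently (Fisher's exact p = 1.08e-26). Both called 4 lower against 1.51 (Fisher's exact p = 0.0644), and 1 gene went opposite ways against 2.89. Genes are neither independent nor equally easy to call, so these p-values do not measure chance. The 23 included Gzmc, Xcl1, Ms4a4c, Tnfrsf9, Cd96, Rgs1, Lilr4b and Spin2c. They also included antigen-processing genes: the immunoproteasome subunits Psmb8 (0.40 in CD11b+ cells, 0.52 in CD27+ cells) and Psmb9 (0.72, 0.50), the proteasome activators Psme1 (0.54, 0.48) and Psme2 (0.64, 0.62), and the class I molecules H2-T23 (0.56, 0.62) and H2-Q7 (0.53, 0.67). The shared falls were Rasgrp2 (-2.58, -1.76), As3mt (-1.97, -0.82), Nr4a1 (-1.18, -0.96) and D1Ertd622e, a gene of unknown function (-1.31, -1.02). Antigen-processing genes and D1Ertd622e are outside the rule for naming genes and were singled out after their values were seen. Over all genes the log2 differences correlated weakly across genes, which are not independent replicates (Pearson r = 0.0881, Spearman rho = 0.133).

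The comparison of CD27+ with CD11b+ cells among CD69- cells asks how maturation stages differ outside the CD69+ pool. In CD27+ cells the lists of mature, cytotoxic and NK identity genes fell, and those of immature and ILC1 genes rose. The largest rises were again stromal transcripts, and CD3 and T cell receptor genes rose as well.

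Mature genes fell, 10 of 12 in both counts and 0 rising (camera adjusted p = 2.4e-19; with an estimated correlation 0.000403). Cma1 fell by 5.15 (SE 0.49), from 871 ± 189 to 24.0 ± 9.63 CPM. S1pr5 stood at a log2 difference of -3.85, Irf8 at -2.12 and Klrg1, an inhibitory receptor of terminal NK cells, at -4.39 (SE 0.55), going from 784 ± 163 to 37.6 ± 24.6 CPM. Cx3cr1 stood at -4.78, Ccl9, a myeloid-attracting chemokine, at -6.76, Cym at -5.11 and Cdc20b, a relative of a mitotic regulator, at -4.28, all in 6 of 6 libraries. Tmtc1, a mannosyltransferase, had 3 counts in CD27+CD69- libraries and a count ratio of 76.1 between CD11b+ and CD27+ (95% interval 25.8 to 371). Cytotoxic genes fell, 6 of 12 with 2 rising, or 8 and 2 when adjusted over the list alone (camera adjusted p = 3.59e-09; with an estimated correlation 0.00412): Gzma at -1.70, Prf1 at -2.60, Gzmb, the main apoptosis-inducing granzyme, at -3.13, and Nkg7, a granule membrane protein, at -0.89. NK identity genes fell, 13 of 16 with 1 rising, or 15 and 1 when adjusted over the list alone (camera adjusted p = 2.4e-19; with an estimated correlation 0.00242): Klra9 at -2.48, Serpinb9, a granzyme B inhibitor, at -1.15, and Ncr1 (NKp46, an activating receptor) at -1.08 (SE 0.10, adjusted p = 5.31e-08). Klrb1c, the NK1.1 antigen gene, fell by 0.94 (SE 0.11, adjusted p = 9.09e-07, 6 of 6). Activating receptors fell, 10 of 13 with 1 rising in both counts (camera adjusted p = 5.94e-12; with an estimated correlation 0.0106), with Fcer1g, a signalling adaptor, at -0.85 and Slamf7 at -1.48. Beside these falls, 22 of 24 pan-leukocyte genes were also lower in CD27+CD69- libraries, with a median of -0.52.

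Factors acting on dendritic cells fell, 4 of 8 with 1 rising in both counts (camera adjusted p = 3.22e-05; with an estimated correlation 0.0242): Ccl5 at -1.67, Ccl3 at -2.88 and Ifng, the type II interferon, at -1.32. Effector cytokines were called down with 5 of 11 falling and 2 rising in both counts (camera adjusted p = 0.00477; adjusted p = 0.131 with an estimated correlation), although the median was 0.72 and the mean -0.15. STAT5 targets fell, 8 of 22 with 2 rising, or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.00344; adjusted p = 0.169 with an estimated correlation), with Ccnd3 at -1.46, Ccnd2, another cyclin, at -1.08 and Odc1 up by 1.17. In the receptor and JAK-STAT5 list 3 of 14 fell and 0 rose, or 4 fell when adjusted over the list alone (camera adjusted p = 0.0213, and adjusted p = 0.145 with an estimated correlation). Il2rg stood at -0.48 (SE 0.11, adjusted p = 0.00386, 6 of 6). It was at -0.21 (adjusted p = 0.343) with melanoma and macrophage and at -0.24 (adjusted p = 0.979) with fibroblast and melanoma covariates. Pik3cd, a lipid kinase, stood at -0.65 and Stat3, a cytokine signal transducer, at -0.54. Both changed sign with fibroblast and melanoma covariates. Immediate early genes fell, 7 of 22 with 1 rising, or 11 and 3 when adjusted over the list alone (camera adjusted p = 8.37e-06; adjusted p = 0.0801 with an estimated correlation), with Dusp2, a MAP kinase phosphatase, at -1.12. Egress genes fell, 3 of 9 with 1 rising, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.230 with an estimated correlation). Klf2 stood at -1.53, and Ccr7, the lymph node homing receptor, was up by 5.55. With fibroblast and melanoma covariates the egress list changed sign and did not pass.

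Immature genes rose, 11 of 14 with 0 falling, or 12 when adjusted over the list alone (camera adjusted p = 6.55e-12; with an estimated correlation 0.00242), with Emb up by 2.74, Ltb by 3.68 and Cxcr3, a receptor for interferon-induced chemokines, by 1.90. ILC1 and residency genes rose, 7 of 15 with 1 falling, or 8 and 1 when adjusted over the list alone (camera adjusted p = 0.000204; with an estimated correlation 0.0106), with Gpr183 up by 4.23, Cxcr6, a residency chemokine receptor, by 4.64 and Tmem176b, a membrane protein of innate lymphoid cells, by 4.18. T cell genes rose, 10 of 11 with 0 falling in both counts (camera adjusted p = 1.99e-08; adjusted p = 0.0585 with an estimated correlation; median 4.78 with genes at 0 counts set to their bound), with Cd3g, a chain of the T cell receptor complex, up by 6.66. Interferon genes rose, 11 of 22 with 0 falling, or 16 and 1 when adjusted over the list alone (camera adjusted p = 7.73e-07; adjusted p = 0.0780 with an estimated correlation), with Bst2 up by 1.41 and Rtp4, an interferon-induced chaperone, by 2.11. Ribosomal protein genes rose, 14 of 24 with 0 falling, or 16 when adjusted over the list alone (camera adjusted p = 1.82e-08; adjusted p = 0.237 with an estimated correlation), with Rps19 up by 0.77.

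Several rises lay beside the stromal RNA. Hypoxia genes rose, 8 of 16, or 9 when adjusted over the list alone (camera adjusted p = 0.000299; adjusted p = 0.145 with an estimated correlation), with Hif1a, the hypoxia-inducible factor, up by 1.07 and Bnip3, a mitophagy receptor, by 3.04. Glycolysis genes rose, 8 of 14 with 1 falling, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.000651; adjusted p = 0.239 with an estimated correlation), with Ldha, lactate dehydrogenase, up by 0.78. With fibroblast and melanoma covariates both lists changed sign and did not pass (adjusted p = 0.688 and 0.813). Cell cycle genes rose, 5 of 24, or 7 when adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.173 with an estimated correlation), with Tyms, thymidylate synthase, up by 1.74. The summed fibroblast genes were at 4338 ± 3321 CPM in CD27+CD69- and 1.49 ± 3.21 CPM in CD11b+CD69- libraries. Col3a1 (ENSMUSG00000026043), a fibrillar collagen chain, had 1300.4 ± 999 CPM against 1 count, a count ratio of 17774 with a 95% interval from 3189.6 to 702091. Sparc, a collagen-binding matrix protein, had 2 counts in the other population, and a count ratio of 11105 with an interval from 3074 to 91702. Serping1 (a complement inhibitor), Fn1 (fibronectin), Serpina3n (a protease inhibitor), Serpinf1 (an angiogenesis inhibitor), Cd34 and Mpzl1 (an adhesion protein) were at least 3299-fold, 2219-fold, 1830.3-fold, 1064-fold, 951.6-fold and 860.7-fold higher, against 0 counts.

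The test called 1304 genes, 786 higher and 518 lower, and 2501 had an unadjusted p under 0.05. Among genes over 10 CPM in the CD69+ populations it called 521 higher and 496 lower, and with no filter 1480 and 453. Among named genes and the 4 members of each list with the smallest p, 61 passed the threshold. Of these, 5 passed in every alternative fit that tested them, and 55 did not pass with fibroblast and melanoma marker levels as covariates.

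**Figure D2:**
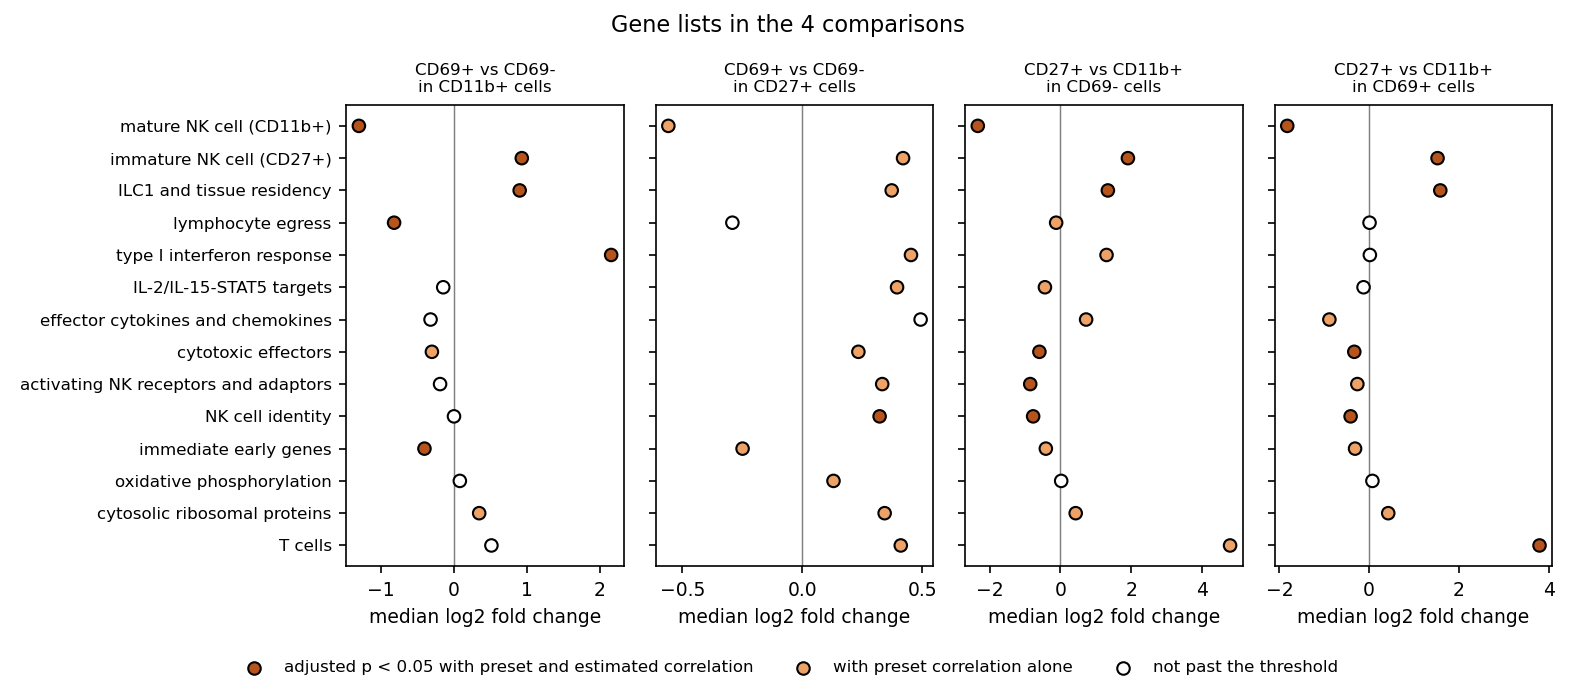
Median log2 difference of the measured members of 14 gene lists in each pairwise comparison, on a scale of its own in each panel. Members at 0 counts in a population are set to their bound. Dark points passed camera's threshold with the preset and the estimated correlation, light points with the preset correlation alone, and white points with neither. The mature NK cell list lies below 0 in all 4 comparisons.

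Among CD69+ cells, the comparison of CD27+ with CD11b+ cells asks the same question within the CD69+ pool, where fibroblast RNA was low in both populations (27.5 ± 42.7 and 0 CPM). The lists of mature, cytotoxic and NK identity genes fell in CD27+ cells here too. Immature and ILC1 genes rose, and T cell receptor genes gave the largest rises.

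Mature genes fell, 7 of 12 with 1 rising, or 10 and 1 when adjusted over the list alone (camera adjusted p = 1.21e-16; with an estimated correlation 0.000662), with Gzma at -1.90, Irf8 at -1.44 and Cma1 at -3.66. Cytotoxic genes fell, 5 of 12 with 0 rising, or 6 and 1 when adjusted over the list alone (camera adjusted p = 1.54e-09; with an estimated correlation 0.00310), with Prf1 at -1.77, Gzmb at -2.28 and Nkg7 at -0.36. Factors acting on dendritic cells fell, 4 of 8, or 5 when adjusted over the list alone (camera adjusted p = 1.22e-07; with an estimated correlation 0.00580): Ccl3 at -4.03 (SE 0.36), going from 759 ± 273 to 46.4 ± 25.8 CPM, and Ifng at -1.32. Effector cytokines fell, 4 of 11 with 1 rising, or 6 and 2 when adjusted over the list alone (camera adjusted p = 0.00110; adjusted p = 0.0919 with an estimated correlation). Ccl9 had 1 count in CD27+CD69+ libraries and a count ratio of 361 (95% interval 64.4 to 14304). Cym stood at -5.40, Cdc20b at -5.30 and Entpd1, the ATP-degrading enzyme CD39, at -3.48, all in 6 of 6 libraries.

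NK identity genes fell, 8 of 16 with 1 rising, or 11 and 1 when adjusted over the list alone (camera adjusted p = 1.16e-13; with an estimated correlation 0.00628), with Klrb1c at -0.67 (SE 0.11, adjusted p = 0.000544, 6 of 6) and Cd7, a surface antigen of lymphocytes, up by 0.99. Ncr1 fell by 0.47 (SE 0.10, adjusted p = 0.0102, 6 of 6), and not past the threshold without replicate 3 (-0.39, adjusted p = 0.0867) or without replicate 5 (-0.44, adjusted p = 0.0697). Activating receptors fell, 4 of 13 with 0 rising, or 5 and 1 when adjusted over the list alone (camera adjusted p = 1.37e-05; adjusted p = 0.101 with an estimated correlation). The receptor and JAK-STAT5 list was called down with 0 of 14 past the threshold in either count (camera adjusted p = 0.00819; adjusted p = 0.101 with an estimated correlation). STAT5 targets did not move as a set, with 3 of 22 down and 1 up, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.379; Tnfrsf9 at -0.96, Odc1 up by 0.71).

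Immature genes rose, 9 of 14, or 11 when adjusted over the list alone (camera adjusted p = 2.53e-19; with an estimated correlation 0.00033), with Emb up by 1.98, Cd160 by 1.61 and Cxcr3 by 1.44. ILC1 and residency genes rose, 4 of 15, or 7 when adjusted over the list alone (camera adjusted p = 4.44e-06; with an estimated correlation 0.00296), with Gpr183 up by 2.69, Cxcr6 by 4.76 and Rora, a transcription factor of innate lymphoid cells, by 1.61. T cell genes rose, 8 of 11, or 9 when adjusted over the list alone (camera adjusted p = 1.13e-15; with an estimated correlation 0.00628): Cd3e, a chain of the T cell receptor complex, by 6.48 (SE 0.62), from 1.45 ± 2.26 to 139 ± 45.0 CPM, and Trac, the receptor alpha constant gene, by 2.57. From 0 counts, the gamma constant genes Tcrg-C2 and Tcrg-C1 were at least 430.6-fold and 223-fold higher, the variable genes Trbv17, Trgv2 and Trbv3 at least 290.1-fold, 139.5-fold and 102-fold, and Ccr8, a chemokine receptor of tissue lymphocytes, at least 148-fold. Ifngas1, a non-coding RNA near Ifng, rose by 6.64. Immediate early genes fell, 1 of 22, or 4 when adjusted over the list alone (Dusp2 at -0.95; camera adjusted p = 0.000407; adjusted p = 0.170 with an estimated correlation). Heat shock genes fell, 1 of 13, or 4 when adjusted over the list alone (Dnajb1, a co-chaperone, at -0.82; camera adjusted p = 0.000296; adjusted p = 0.197 with an estimated correlation). Cell cycle genes rose, 1 of 24, or 4 when adjusted over the list alone (Stmn1 by 2.32; camera adjusted p = 0.000755; adjusted p = 0.254 with an estimated correlation). Ribosomal protein genes rose, 8 of 24, or 20 when adjusted over the list alone (Rpl4, a large-subunit protein, by 0.48; camera adjusted p = 8.49e-20; adjusted p = 0.0860 with an estimated correlation).

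The test called 200 genes, 104 higher and 96 lower, and 1205 had an unadjusted p under 0.05. The small excess of rises turned without the 3 CD27+CD69- libraries with most stromal and melanoma RNA (98 higher, 110 lower), among genes over 10 CPM in the CD69- populations (82 and 96) and with no filter (80 and 83). Among named genes and the 4 members of each list with the smallest p, 50 passed the threshold. Of these, 31 passed in every alternative fit that tested them. The CD27 comparisons of CD69- and CD69+ cells share no libraries either, but again share replicate numbers and 1 fit. Both called 85 genes higher (7.76 expected) and 82 lower (4.72 expected), with 2 opposite (12.3 expected). The expected numbers again take genes as independent, which they are not. The log2 differences correlated across genes with r = 0.558 and rho = 0.379.

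The CD69 difference itself differed between CD27+ and CD11b+ cells for 61 genes, 25 higher and 36 lower in CD27+ cells, and 997 had an unadjusted p under 0.05. The values are signed: a higher one can be a rise in CD27+ cells or a fall in CD11b+ cells. Interferon genes and several NK receptor genes were among them. Of 22 interferon genes 5 had a lower signed CD69 difference in CD27+ cells and 0 a higher one, or 8 when adjusted over the list alone (camera adjusted p = 1.8e-10; adjusted p = 0.0749 with an estimated correlation). Ifi44 stood at 0 CPM in CD11b+CD69-, 75.1 ± 45.0 in CD11b+CD69+, 25.9 ± 11.3 in CD27+CD69- and 48.0 ± 26.7 in CD27+CD69+ libraries, and Oasl2, an oligoadenylate synthetase relative, at 4.18, 47.4, 47.9 and 55.1 CPM in the same order. NK identity genes had a higher signed CD69 difference in CD27+ cells, 2 of 16, or 6 when adjusted over the list alone (Klra9 by 1.53, Nkg7 by 0.52; camera adjusted p = 9.16e-10; adjusted p = 0.0749 with an estimated correlation). The same held for activating receptors, 2 of 13 with 0 lower, or 7 and 1 when adjusted over the list alone (Slamf7 by 1.27, Klrc2 by 0.97; camera adjusted p = 1.6e-07; adjusted p = 0.118 with an estimated correlation). For STAT5 targets it was 2 of 22, or 3 when adjusted over the list alone (Ccnd3 by 0.90 and Bcl2, a survival factor, by 0.74; camera adjusted p = 0.00801; adjusted p = 0.264 with an estimated correlation). Camera also called the hypoxia, glycolysis, heat shock and immature lists lower and the egress and cytotoxic lists higher, with adjusted p from 8.07e-06 to 0.0129, and from 0.142 to 0.264 with an estimated correlation. Fibroblast RNA was high in CD27+CD69- libraries alone, which bears on this contrast too: with fibroblast and melanoma covariates 0 genes were higher and 7 lower. None of these calls passed with an estimated correlation. Among named genes and the 4 members of each list with the smallest p, 16 passed the threshold. Of these, 0 passed in every alternative fit that tested them.

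**Figure D3:**
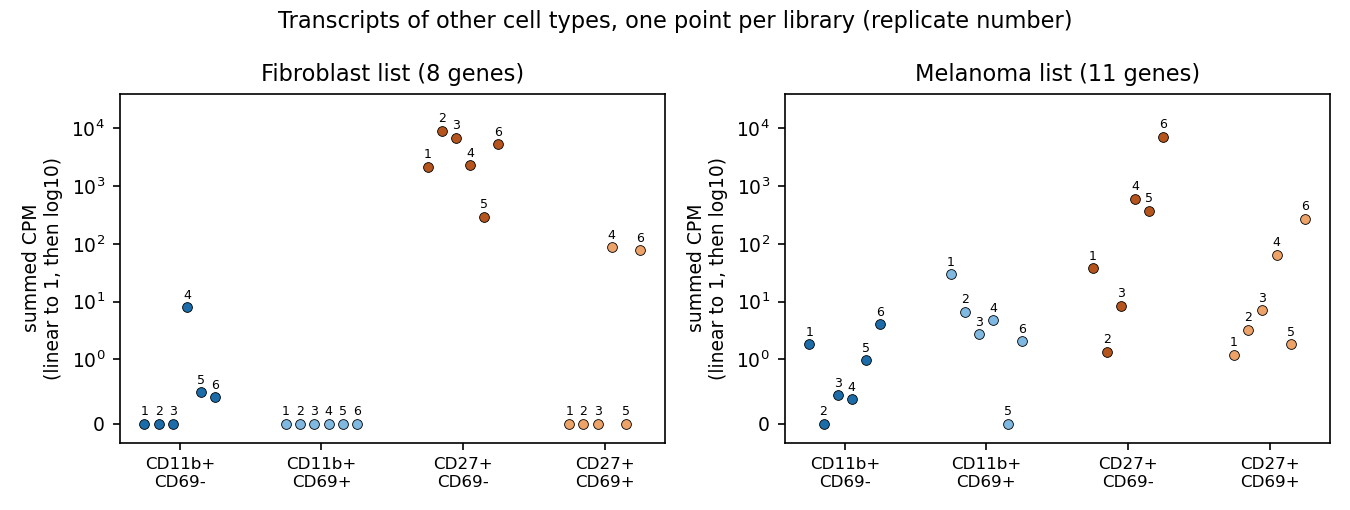
Summed CPM of 8 fibroblast and 11 melanoma marker genes in each of the 24 libraries, labelled by replicate number, on an axis linear to 1 and log10 above. The CD27+CD69- libraries hold 294 to 9093 CPM of fibroblast transcripts, and no other population has a library above 87.0.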

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

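The tests of fibroblast and melanoma transcripts, of the cytotoxic list after a reference list is taken off and of the correlation among T cell genes were chosen after the result was seen. The tests of the median of cytotoxic against pan-leukocyte genes, of T cell against NK identity genes and of other splits were written before.

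The first pattern is fibroblast and melanoma RNA in the CD27+CD69- libraries. Replicates 1 to 6 held 2172, 9093, 6837, 2282, 294 and 5348 CPM of the 8 fibroblast genes, and 7142 CPM of melanoma genes set replicate 6 far from the others (1.37 to 606). The most abundant of these genes were Dcn (1523 CPM), Col3a1 (1300.4) and Lum (495), which encode matrix proteins, and among melanoma genes Dct (376) and Tyrp1 (296), pigment genes, and Ptgds (252), a prostaglandin synthase. In 5 of 6 libraries at least 6 of the 8 fibroblast genes exceeded 10 CPM, so stromal and tumour cells in the CD27+CD69- sort are a candidate explanation, which a sort that gates out CD45-negative cells would remove. RNA carried over through the whole batch is argued against by the CD11b+ libraries, whose median was 0% of that of the CD27+CD69- libraries, and expression of melanoma genes by the NK cells themselves by a 71.3-fold range that remained without the highest and the lowest library. For the fibroblast genes that range was 3.15-fold, so expression in the NK cells and other cells in the sort cannot be told apart on it.

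The second pattern is lower cytotoxic transcripts in CD27+CD69- than in CD11b+CD69- libraries. The median of the 12 cytotoxic genes was -0.60 and that of 24 pan-leukocyte genes -0.52, with 8 of 12 and 22 of 24 lower. The difference of these medians was -0.077 (95% interval -0.89 to 0.71), which decides nothing, since members past the threshold went both ways. The pan-leukocyte median had a 95% interval of -0.71 to -0.35. The intervals of list medians resampled the genes of a list, not libraries, so they leave out the spread between libraries. Dilution as the whole cause was tested by taking the lower bound of a reference list's interval off the CD27+ libraries and testing what was left of the cytotoxic list with fry of limma, with p adjusted over 4 tests. After the pan-leukocyte bound the list was down and did not pass (adjusted p = 0.0687), and after the bound of 14 NK identity genes (-1.04) it was up (adjusted p = 0.111). Among CD69+ cells, where fibroblast RNA was low and the pan-leukocyte median was -0.098, the list was down after the pan-leukocyte bound (adjusted p = 0.000401) and not after that of NK identity genes (up, adjusted p = 0.505). Stromal RNA would lower both references, while T cells would lower NK identity genes and bring pan-leukocyte genes of their own. Maturation may also lower NK identity genes, so maturation state and dilution by other leukocytes cannot be told apart on these lists.

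The third pattern is CD3 and T cell receptor transcripts in CD27+ libraries. The 11 T cell genes correlated across the 12 CD27+ libraries with a mean of 0.566, above 0.0963, the 95th percentile of 10000 matched random sets. Genes that vary together for any reason would exceed such sets, so this does not single out T cells. T cells in the CD27+ sort are a candidate source, which a gate on surface CD3 would remove. Summed T cell markers stood at 2369 ± 637 (CD69-) and 3282 ± 571 CPM (CD69+), against 1120 and 1476 in the CD11b+ libraries. They were led by Trbc1 (888 and 1065 CPM, but also 807 and 1012 in the CD11b+ libraries), Trbc2 (322 and 440, against 152 and 161) and Cd3d (257 and 429, against 3.33 and 12.3). Transcription of these genes in the NK cells stays open: T cell genes followed the 16 NK identity genes with Pearson r = 0.636 (permutation p = 0.0329) and Spearman rho = 0.322 (permutation p = 0.309). Without the 2 farthest libraries r was -0.0866, so the relation rests on those 2 libraries and the explanations cannot be told apart.

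A sample stood apart from its group in 8 of 72 groups of 6 tested. Chance gives about 1 in 20 for normally distributed values. CPM that are skewed or mostly 0 do not meet that condition, so no excess over chance is shown. Of the 8, 1 was the melanoma sum of CD27+CD69- replicate 6, given above. Mitochondrial transcripts made up 1.31% of counts in CD11b+CD69+ replicate 4 against 0.706 to 0.886% in the others. Fibroblast genes summed to 8.02 CPM in CD11b+CD69- replicate 4 against 0 to 0.492. Melanoma genes summed to 29.9 CPM in CD11b+CD69+ replicate 1 against 0 to 6.65, and to 273 in CD27+CD69+ replicate 6 against 1.21 to 65.0. T cell genes summed to 1768 CPM in CD11b+CD69+ replicate 3 against 1366 to 1492. Cd69 was at 380.2 CPM in CD27+CD69- replicate 6 against 733 to 917. Il2ra was at 10.7 CPM in CD11b+CD69- replicate 3 and 0 in the others.

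The CD69 difference differed between CD27+ and CD11b+ cells for 61 genes. As a signed value it was higher in CD27+ cells for Ero1lb, an oxidase of protein folding (2.63), Gatsl3, an arginine sensor of mTORC1 (2.07), Ly6c2 (1.95), Klra9 (1.53), Slamf7 (1.27), Klrc2 (0.97), Ccnd3 (0.90), Bcl2 (0.74) and Nkg7 (0.52). It was lower for Oasl2 (-3.29), Bst2 (-1.40) and Hif1a (-1.20). The fitted values of Lama4, a laminin chain (-13.45), S100a16, a calcium-binding protein (-13.17), Adgrd1, an adhesion receptor (-12.78), Ifi44 (-9.43) and Rsad2 (-9.04) depend on the prior count, since a group had 0 counts. Lama4, S100a16 and Adgrd1 stood at 47.0, 134 and 42.4 CPM in CD27+CD69- libraries, with 0 counts in CD11b+CD69- libraries.

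Other groupings of the same libraries were compared with the real counts of genes. In 100 splits of 12 libraries only 1 split, the real one, called as many genes in each pairwise comparison. Every other split mixed the 2 populations, so their difference widened the spread within its groups and lowered its count. The splits therefore do not show how many of the calls are false. Fits to those 12 libraries called 373, 150, 885 and 228 genes, for CD69 in CD11b+ and in CD27+ cells and for CD27 against CD11b in CD69- and in CD69+ cells, and the highest other splits called 1, 2, 1 and 48. In 50 groupings of all 24 libraries again only 1, the real one, called as many. It called 61 genes for the difference between CD69 differences (highest other 0) and 1483 for any difference (highest other 1). Those groupings also broke up the separate CD27 and CD69 differences, so they are no test of the 61 genes alone.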

How the results depend on the processing

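The fits with fibroblast and melanoma covariates, without 3 CD27+CD69- libraries, and limited to genes over 10 CPM in the other 2 populations were chosen after the results were seen. Changes are described as numbers of genes or lists past the threshold, and where no construction is named the cause was not tested.

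DESeq2 size factors and thinning to the smallest total kept every count of genes, and of lists in the 4 pairwise comparisons, within 1.5 times its value. The fit to only the 2 populations compared, run for the 4 pairwise comparisons alone, did so there. So did the replicate number as a block, although the labels do not say what the numbers mark: same-numbered libraries correlated between -0.029 and 0.207 (median 0.0020, 36 pairs), and 5 of 24 samples correlated best with one of their own number. The highest was the CD27+ pair of replicate 6, and melanoma genes were highest in replicates 6 and 4 of both CD27+ populations (7142 and 606 CPM in CD69-, 273 and 65.0 in CD69+). The block gave 273 genes for CD69 in CD11b+ cells, 254 in CD27+ cells, 1275 for CD27 against CD11b in CD69- cells, 198 in CD69+ cells and 65 for the difference between CD69 differences. Similar counts can hold different genes. Of the genes called in the analysis reported, the fit to only the 2 populations called 79.2, 58.5, 64.1 and 78.5% again, in that order of pairwise comparisons. Its filter had left some of them out. No library fell outside the quality rule, so the fit without such libraries was not run.

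For CD69 in CD11b+ cells (289 genes), no low-count filter gave 188 and the DESeq2 Wald test 519. Leaving out 1 replicate number gave 183 to 256, with 183, 183 and 187 without replicate 2, 3 and 4. For CD69 in CD27+ cells (195 genes) the counts were 405 with no filter, 331 with a mean of at least 5 CPM, 448 with DESeq2, 362 with limma-voom, 89 with melanoma and macrophage covariates, 8 with fibroblast and melanoma covariates, 68 without the 3 libraries and 80 among genes over 10 CPM in CD11b+ cells. Leaving out 1 replicate number gave 106 to 252, with 106, 126, 112 and 252 without replicate 2, 3, 4 and 5.

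For CD27 against CD11b in CD69- cells (1304 genes) the counts were 615 with melanoma and macrophage covariates, 67 with fibroblast and melanoma covariates and 791 without the 3 libraries, and leave-one-out gave 900 to 1320. In CD69+ cells (200 genes) DESeq2 gave 355, and leave-one-out 115 to 188, with 118, 125 and 115 without replicate 2, 4 and 5. For the difference between CD69 differences (61 genes) the counts were 213 with DESeq2, 96 with limma-voom, 16 with melanoma and macrophage covariates, 7 with fibroblast and melanoma covariates and 19 without the 3 libraries. Leave-one-out gave 17 to 51, with 17, 21, 18 and 39 without replicate 2, 3, 4 and 5. For any difference among the populations (1483 genes) they were 3251 with no filter, 2246 with DESeq2 and 727 with fibroblast and melanoma covariates, and leave-one-out gave 1092 to 1371. By construction, the fibroblast covariate nearly coincides with membership in the CD27+CD69- population, so it removes that population's own differences too, and omission of the 3 libraries leaves 3 in 1 group.

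Lists past the threshold with an estimated correlation were 6 of 10, 2 of 19, 7 of 18 and 7 of 14 in the order of the comparisons above. For CD69 in CD27+ cells fry called 10 lists and the fit with fibroblast and melanoma covariates 9. Leave-one-out gave 8 to 13, 14 to 19, 16 to 19 and 14 to 15 lists. The correlation of the CD69 differences across genes, 0.0881, was 0.0277 with no filter, 0.0249 with DESeq2 and 0.0495 with fibroblast and melanoma covariates, and 0.0610 to 0.0911 in leave-one-out.

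Flt3l passed the threshold in no comparison under any alternative. Its CD69 difference in CD27+ cells changed sign with fibroblast and melanoma covariates (-0.17). Its CD27 difference in CD69- cells was 0.30 with melanoma and macrophage covariates, 0.57 with fibroblast and melanoma covariates and 0.043 without the 3 libraries.

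Other genes changed sign too, of which Cd27, Klrb1c, Il2ra, Il2rb and Il15ra had not passed the threshold in the comparisons concerned. For CD69 in CD27+ cells, fibroblast and melanoma covariates gave -0.12 for Cd27, -0.12 for Klrb1c, -0.31 for Il2rb and 1.59 for Col3a1. Melanoma and macrophage covariates gave -0.14 for Klrb1c and -0.14 for Il2rb, omission of the 3 libraries gave -0.068 for Il2rb, and leave-one-out gave -0.026 to 0.096 for Klrb1c. For CD69 in CD11b+ cells leave-one-out gave -0.051 to 0.091 for Il2rb. For CD27 in CD69- cells, fibroblast and melanoma covariates gave -2.99 for Il2ra, 0.11 for Il2rb, 0.034 for Pik3cd, 0.15 for Stat3, -0.29 for Hspe1, -0.46 for Ero1l, -0.040 for Gapdh, -0.15 for Aldoa, -0.10 for Tpi1 and -2.90 for Col1a2. Melanoma and macrophage covariates gave -0.055 for Hspe1, and leave-one-out -0.043 to 5.92 for Il2ra, where 5.92 is the fit without replicate 3, against 0 counts, and depends on the prior count. For CD27 in CD69+ cells Il2ra was 0.42 with limma-voom, 0.58 with the block and -0.43 to 0.41 in leave-one-out.

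For the difference between CD69 differences, fibroblast and melanoma covariates gave 2.79 for Il2ra, -0.39 for Il2rb and 0.42 for Il15ra. Melanoma and macrophage covariates gave -0.23 for Il2rb, and omission of the 3 libraries -0.12 for Il2rb and 0.32 for Il15ra. Leave-one-out gave -6.00 (again without replicate 3 and no size) to 0.46 for Il2ra, -0.035 to 0.34 for Il2rb and -0.68 to 0.37 for Il15ra.

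Some of the genes named in every comparison passed only in alternatives, besides Il2ra and Cd69. For CD69 in CD11b+ cells these were Itgam, Ncr1 and Klrb1c in the fit to only the 2 populations (adjusted p = 0.0474, 0.0182 and 0.0301), and Cd27 with melanoma and macrophage covariates (0.0377) and without replicate 1 (0.0369). For CD27 in CD69- cells Il2rb passed with limma-voom (0.00415), the block (0.0409) and without replicate 1 (0.000900), and in CD69+ cells in the fit to only the 2 populations (0.0103). For the difference between CD69 differences Ncr1 passed with a mean of at least 5 CPM (0.0477), DESeq2 (0.0106) and limma-voom (0.0396). With fibroblast and melanoma covariates Itgam (-1.94, adjusted p = 0.898) and Klrb1c (-0.72, adjusted p = 0.107) no longer passed for CD27 in CD69- cells, where they had -2.86 and -0.94 in the analysis reported.

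Lists are given as signed -log10 adjusted p. For CD69 in CD27+ cells, fibroblast and melanoma covariates gave -0.0402 for cytotoxic genes, 0.511 for heat shock, -0.376 for NF-kB targets, -0.0840 for interferon genes, 0.376 for hypoxia and 1.78 for glycolysis. Melanoma and macrophage covariates gave 0.0828 for heat shock and 1.61 for glycolysis, and no filter gave 0.0916 for glycolysis. For CD27 in CD69- cells, fibroblast and melanoma covariates gave 0.344 for egress, -0.163 for hypoxia and -0.0898 for glycolysis.

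Over all alternatives of 247 results of named genes, a gene counted once per comparison, 3655 kept their direction and side of the threshold, 603 fell short of it, 24 newly passed and 35 changed sign. For 61 list results past the threshold these were 1009, 133, 0 and 12. On simulated counts for CD69 in CD11b+ cells, the edgeR test recovered 39% of genes changed 2-fold and 72% changed 4-fold with 1.68% false calls. The DESeq2 test recovered 46% and 80% with 9.59% false calls, so most 2-fold changes were missed at the simulated depth and spread.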

Other observations

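Of 33 lists, 6 had too few measured members for a test: melanoma cells (0 of 11 genes), red blood cells and platelets (0 of 8), neutrophils (1 of 9), endothelial cells (1 of 7), ILC2 and ILC3 (1 of 10) and B cells (2 of 9). The filter needs counts in about as many libraries as a group holds, so a transcript abundant in a few libraries, such as Dcn, was not tested.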
